A study of Mus musculus with 13 samples.

How the data were processed

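RNA was sequenced from 13 pools of mouse oocytes, each of 25 cells per the labels. The pools fall into 4 groups: germinal vesicle (GV) oocytes of wild-type (WT) females (n = 3), GV oocytes of females lacking the long noncoding RNA Sirena1 (Null, n = 3), metaphase II (MII) eggs of WT females (n = 3) and MII eggs of Null females (n = 4). Per the labels, 0.2 pg of Renilla luciferase RNA was added to each sample as a spike-in. The deposited table holds raw counts of reads per gene of Ensembl release 93, with no normalization, for 54232 genes in 13 columns. The submitters' processing notes list STAR 2.5.3a and bedtools 2.26.0 and the mouse genome build GRCm38.p6. The counting tool, its strand setting and its handling of reads that map to several places are not given in the sources used here. The table holds 0 lines that are not genes, so no spike-in count was available.

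Gene IDs were paired with symbols through a table of names, in which 54079 IDs had a symbol and 153 had none. Sirena1 stands in the table under the symbol C86187, which the RefSeq table of the same genome build lists with Sirena1 as a synonym. Coordinates are those of that RefSeq table. It gives none for the mitochondrially encoded mRNAs or for the pseudogene Gm28438.

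Counts were fitted with edgeR 4.0.16 in R 4.3.3. All 13 libraries entered 1 model with 4 groups, scaled with TMM factors. Genes were kept with filterByExpr by group, which left 20143 genes. Of the genes left out, 14637 had no count in any library. The functions glmQLFit (robust) and glmQLFTest tested 5 comparisons, each two-sided. These were Null against WT in GV oocytes, Null against WT in MII eggs, the difference between these effects, MII against GV in WT, and MII against GV in Null. Adjusted p values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05 and no minimum fold change. Levels are TMM-scaled CPM (the usual count unit scaled to library size), given as mean ± SD over libraries, and log2 fold changes are given with the standard error (SE) of the fit. The SE treats the spread of a gene as shared by all groups. The groups differed in this spread. The chi-square of counts between 2 replicates, per degree of freedom, was 5.37 to 8.64 in GV WT and 11.3 to 38.3 in GV Null. It was 8.44 to 13.3 in MII WT and 11.4 to 31.5 in MII Null.

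Total counts per library ran from 30867614 to 41285507. A count of 3, taken as the detection limit, corresponds to 0.0727 to 0.0972 CPM per library. Reads carry no molecular identifiers, so these limits cover counting error alone.

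The same tests were run on simulated counts with known changes, drawn with the means, library sizes and dispersions of these libraries. Apart from the changes put in, each gene had the same mean in all libraries, and genes varied independently. The simulation thus held no cumulus RNA and no outlying library. In each genotype comparison 200 genes above a minimum level were changed, which eases the Benjamini-Hochberg threshold relative to the 11 real calls. The shares below are thus not the power of the real comparisons. In GV oocytes 50.7% of genes changed 1.5-fold, 65.7% of genes changed 2-fold and 100% of genes changed 4-fold were found, with 11 false calls among 155. In MII eggs the shares were 58.2%, 73.1% and 97.0%, with 7 false calls among 159. For maturation in WT they were 31.3%, 74.6% and 90.9%, with 7 false calls among 138. For maturation in Null they were 49.3%, 85.1% and 92.4%, with 26 false calls among 491. For the difference between stages they were 36.6%, 55.2% and 95.5%, with 17 false calls among 266.

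The tests, the alternatives unless stated otherwise, the rule for naming genes and 17 gene lists were fixed before the data were examined. Named were Sirena1 and its 3 nearest tested neighbours on each side, Elob, the 13 mitochondrially encoded mRNAs and Nnt. For each genotype comparison, the rule took up to 12 genes that rose and 12 that fell with the largest fold among those past the threshold. These had to reach 5 CPM in the higher group, show no overlap between the libraries of the groups and carry a symbol that was not a Gm number or clone name, unless fewer than 5 were left. For maturation in WT the rule took 10 genes per direction with at least 20 CPM, for the difference between stages up to 8 genes by adjusted p, and in each list up to 4 members with the smallest p.

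The lists covered mitochondrially encoded mRNAs, mitochondrial rRNAs, the nuclear-encoded respiratory chain, mitochondrial gene expression and DNA maintenance, mitochondrial distribution and dynamics, Elongin and cullin ligase subunits, RNA interference and microRNA factors, described endo-siRNA targets, and dormant maternal mRNAs. The others covered oocyte-specific and maternal-effect genes, deadenylation and decapping, cytosolic ribosomal proteins, the meiotic spindle and cell cycle, the mitochondrial and integrated stress response, dsRNA sensing and interferon response, cumulus and granulosa cell markers, and C57BL/6 substrain markers. Each list was tested with camera of limma 3.58.1, two-sided, with an inter-gene correlation preset at 0.01, and adjusted over the 17 lists within a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance in one direction and compares them with no other genes.

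The share of counts from mitochondrially encoded mRNAs was compared within each stage by a two-sided exact permutation test. The smallest p it can give is 0.1 for 3 against 3 libraries and 0.0286 for 4 against 3. The plan had put the latter near 0.06. Calls shared between stages were set beside the number expected from independent lists of the same sizes.

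Alternatives were DESeq2 size factors (RLE) and upper-quartile scaling, no filter on low counts, a filter of 5 CPM in at least 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, mitochondrially encoded genes left out of the library sizes, a minimum of 1.5-fold, and leaving out each library in turn. Scaling to the spike-in was planned and could not be run. Replicate numbers were tested as pairs on the correlation of gene levels between groups. The samples with the same number correlated at -0.05 to 0.22 between genotypes, so the numbers were not taken as pairs. All 13 columns were used. Some genes that the naming rule takes are not reported here.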

Results

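RNA sequencing counts were available for 13 pools of mouse oocytes at the GV stage (fully grown, before meiosis resumes) and the MII stage (matured eggs), from WT females and from Null females lacking the long noncoding RNA Sirena1. Total counts ran from 36808560 to 41285507 in the 3 GV WT libraries, from 33360126 to 38637420 in the 3 GV Null libraries, from 31072240 to 33686427 in the 3 MII WT libraries and from 30867614 to 40602239 in the 4 MII Null libraries. The leading principal component of log2 CPM held 65.8% of the variance and parted GV from MII libraries. MII Null replicate 4 lay between the stages, at 25.7 on this axis against 65.8 to 81.4 for the other 3 MII Null libraries.

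The level of the deleted RNA shows whether the genotype labels hold. Sirena1 (C86187, ENSMUSG00000110001) is an 8202 bp lncRNA gene on chromosome 7 from 46967710 to 46975911 in GRCm38.p6. It reached 3006 ± 90.2 CPM in WT GV oocytes (n = 3), where it ranked 11 among all genes, and 4519 ± 221 CPM in WT eggs (n = 3), where it ranked 7. In Null libraries it stood at 24.8 ± 1.58 CPM in GV oocytes (n = 3) and 41.3 ± 4.41 CPM in eggs (n = 4), which is 0.825% and 0.915% of the WT level. The log2 fold changes were -6.92 (SE 0.11, adjusted p = 2.77e-18) and -6.77 (SE 0.09, adjusted p = 3.43e-19), and each Null library lay below each WT library of its stage.

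Of the 6 nearest tested neighbours of Sirena1, 5 did not pass the test at either stage. Tsg101, an ESCRT component, stood at 61.7 ± 3.35 CPM in Null and 61.8 ± 1.31 CPM in WT GV oocytes. Log2 fold changes in GV oocytes and eggs were 0.32 and 0.26 for Uevld, -0.22 and -0.22 for Spty2d1, -0.54 and -0.44 for Gm9999, and 0.20 and 0.79 for Gm32031, which lies near the detection limit. Their smallest adjusted p was 0.709 in GV oocytes and 0.708 in eggs, both for Spty2d1. The exception was Gm19248, a 471 bp pseudogene from 46967147 to 46967617, just left of the Sirena1 gene. It had 0 to 3 counts per GV Null library against 21 to 26 per WT library (adjusted p = 0.0351), and 1 to 3 counts per MII Null library against 19 to 29 per WT library (adjusted p = 0.0131). Gm19248 no longer passed when GV Null replicate 3 or any GV WT replicate was left out, or in eggs when MII Null replicate 1 or any MII WT replicate was left out (highest adjusted p 0.583 in GV oocytes and 0.117 in eggs over the settings tried).

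**Figure D1:**
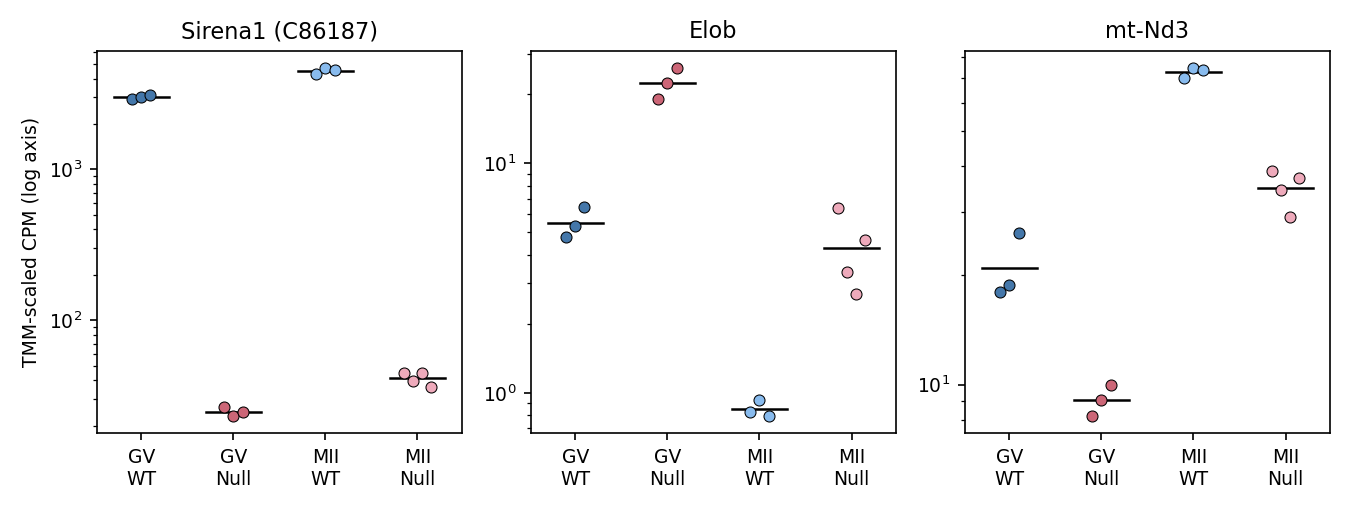
TMM-scaled CPM of Sirena1, Elob and mt-Nd3 in each library, on log axes, with points for libraries and bars for group means (GV WT n = 3, GV Null n = 3, MII WT n = 3, MII Null n = 4). Sirena1 fell from 3006 to 24.8 CPM in GV oocytes, and Elob was higher and mt-Nd3 lower in Null at both stages.

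Null and WT GV oocytes were compared to find transcripts that depend on Sirena1 before maturation. Elob, which encodes the Elongin B subunit of Elongin and of cullin ligases and is a described target of oocyte endo-siRNAs, rose 4.08-fold, from 5.51 ± 0.85 to 22.5 ± 3.47 CPM (log2 2.03, SE 0.23, adjusted p = 0.000773). Tmem267 rose 2.55-fold to 33.4 ± 4.36 CPM (adjusted p = 0.00263), and Zfp385b, a zinc finger gene, rose 1.82-fold to 15.5 ± 0.41 CPM (adjusted p = 0.00263). Tmem267 and Gm19248 did not pass in a fit of only the GV groups, which does not share the spread with eggs. The mitochondrially encoded mt-Nd3, a subunit of respiratory complex I, fell from 21.0 ± 4.53 to 9.06 ± 0.87 CPM (log2 -1.21, SE 0.14, adjusted p = 0.000735). Polb, DNA polymerase beta, fell from 15.1 ± 0.16 to 7.10 ± 1.31 CPM (log2 -1.09, adjusted p = 0.0165).

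In all, 11 of 20143 genes passed in GV oocytes, 5 higher and 6 lower in Null, and 1342 had an unadjusted p under 0.05 where chance gives 1007. None of the 11 showed overlap between Null and WT libraries, a separation that chance gives to 10% of genes with 3 against 3 libraries. Also among those that passed were Sirena1, Gm19248, Gm28438 (10.5 ± 1.08 against 21.1 ± 4.41 CPM, adjusted p = 0.00263), and Gm11598 and Gm8971, named after their values were seen. These last are annotated as pseudogenes, at 3.00 ± 0.37 against 0.63 ± 0.05 CPM and at 2.79 ± 0.43 against 0.55 ± 0.07 CPM. Elobl, an oocyte paralog of Elob, stood at 4632 ± 123 CPM in Null and 3621 ± 79.1 CPM in WT (log2 0.36, adjusted p = 0.804). The fit shares the spread of a gene among all groups, and Elobl ran from 2700 to 5110 CPM in Null eggs. Its log2 fold change in GV oocytes was 0.33 to 0.39 over 17 other settings, and it passed in 1 of them. The count became 139 (111 higher and 28 lower) without GV Null replicate 1, and 6 without GV Null replicate 3, GV WT replicate 1 or GV WT replicate 2, where Polb, Gm11598, Gm19248 and Gm8971 no longer passed (Polb also without GV WT replicate 3, Gm8971 also without GV WT replicate 3 or GV Null replicate 2). It was 24 with DESeq2, 644 (600 higher and 44 lower) with no filter on low counts, 3 with a minimum of 1.5-fold, which kept Sirena1, Elob and Gm11598, and 1, Sirena1, with GV Null replicate 1 as the lone Null library.

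Markers of cumulus and granulosa cells, the somatic cells around the oocyte, were uneven among these libraries. Their summed level was 113, 692 and 282 CPM in GV Null replicates 1, 2 and 3, and 148, 134 and 117 CPM in the GV WT replicates. The list had 20 of 21 measured members above 0, with a median log2 fold change of 2.12 (camera adjusted p = 7.02e-06; adjusted p = 0.553 with an estimated correlation) and no member past the test, over all genes or adjusted over the list alone. Hsd3b1, a steroid-synthesis enzyme, stood at 104 ± 135 CPM in Null and 7.52 ± 6.69 CPM in WT, and Inhba, an inhibin subunit, at 20.9 ± 16.7 and 3.5 ± 1.5 CPM. Without GV Null replicates 2 and 3, a choice made after the data were seen, the list's median was -0.29.

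Among the mitochondrially encoded mRNAs in GV oocytes, 12 of 13 had a positive log2 fold change and mt-Nd3 was the exception. The median was 0.48 (camera adjusted p = 1.27e-06; adjusted p = 0.553 with an estimated correlation). Over all genes only mt-Nd3 passed, and adjusted over the list alone 10 were higher and 1 was lower. mt-Nd1 stood at 362 ± 72.7 CPM in Null and 233 ± 48.5 CPM in WT, and mt-Co1, a subunit of cytochrome oxidase, at 2264 ± 360 and 1618 ± 155 CPM. The share of counts from these mRNAs was 0.575 ± 0.106% in Null and 0.404 ± 0.039% in WT, a ratio of 1.42 (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). GV Null replicates 2 and 3, the ones high in cumulus markers, had shares of 0.673% and 0.589%, and replicate 1 had 0.463%. With replicate 1 as the lone Null library the list's median was 0.23 and the ratio of shares 1.15.

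The other lists in GV oocytes moved by small amounts. The 77 cytosolic ribosomal protein genes had 76 members above 0 and a median of 0.20 (adjusted p = 2.08e-05, or 0.844 with an estimated correlation). Among them Rpl37a stood at 40.5 ± 7.81 CPM in Null and 26.1 ± 4.19 CPM in WT. The list lost its call without the libraries high in cumulus markers (median 0.07, adjusted p = 0.776) and with the cumulus markers as a covariate (median 0.05, adjusted p = 0.874). The 36 meiotic spindle and cell cycle genes had a median of -0.07 (adjusted p = 0.000691; adjusted p = 0.553 with an estimated correlation), with Cdc25b at 28.4 ± 2.06 against 33.9 ± 0.68 CPM. The 20 dormant maternal mRNAs had a median of -0.06 (adjusted p = 0.0145; adjusted p = 0.601 with an estimated correlation), with the checkpoint kinase gene Bub1b at 1211 ± 127 against 1369.7 ± 74.2 CPM. No member of these 3 lists passed, over all genes or adjusted over the list alone. The spindle list lost its call without GV Null replicate 2 (median -0.03), and the dormant list without GV Null replicate 2 or 3 (medians -0.02 and -0.05) and with the filter of 5 CPM (median -0.04, adjusted p = 0.0751). Without both libraries the medians were 0.00245 and 0.081, and with the covariate 0.00525 and -0.00279 (adjusted p = 0.874 for each). The remaining 12 lists did not pass (smallest adjusted p 0.0693, for the mitochondrial rRNAs). Elob was the only member past the test in them, as 1 of 11 Elongin and cullin ligase genes and as 1 of 8 described endo-siRNA targets, and the other 7 such targets included Kifc1 at 18.0 ± 0.80 against 21.8 ± 2.11 CPM.

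**Figure D2:**
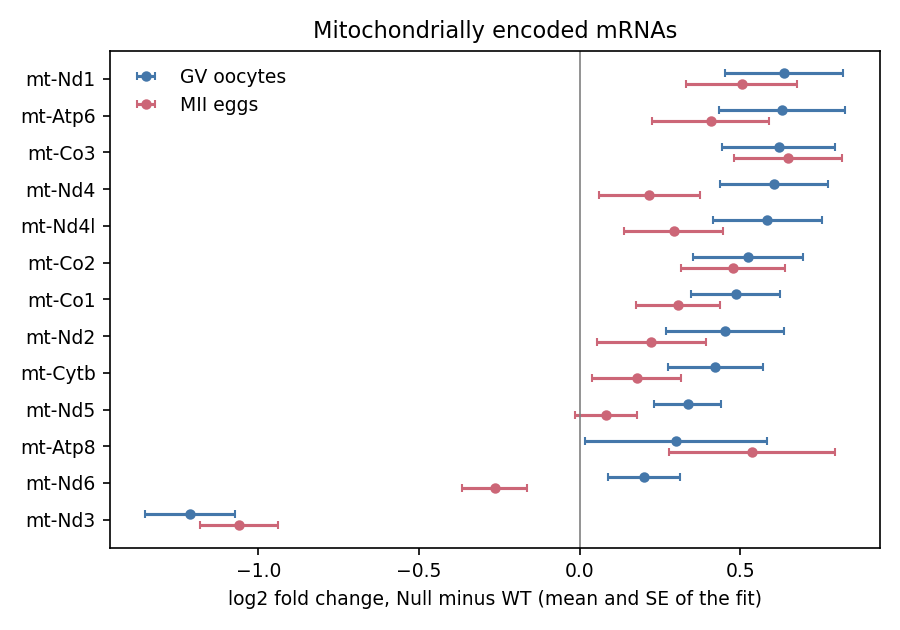
Log2 fold change of Null against WT (horizontal axis) with SE of the edgeR fit for the 13 mitochondrially encoded mRNAs in GV oocytes and MII eggs. mt-Nd3 lies at -1.21 in GV oocytes and -1.06 in eggs, and the median of the list is 0.48 and 0.29.

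The same comparison in MII eggs asked which differences were present after maturation. Elob rose 5.05-fold, from 0.85 ± 0.07 CPM in WT (n = 3) to 4.27 ± 1.63 CPM in Null (n = 4; log2 2.34, SE 0.28, adjusted p = 0.00141). Dhcr7, the last enzyme of cholesterol synthesis, rose 2.02-fold to 20.6 ± 2.31 CPM (adjusted p = 0.0086). mt-Nd3 fell from 72.8 ± 2.29 to 34.9 ± 4.33 CPM (log2 -1.06, SE 0.12, adjusted p = 0.000722). Strap, a WD-repeat protein, fell from 59.2 ± 4.29 to 40.7 ± 3.04 CPM (log2 -0.54, adjusted p = 0.0172), and the lncRNA Gm19276 from 7.92 ± 2.37 to 2.73 ± 0.98 CPM (adjusted p = 0.0326).

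In all, 11 genes passed in eggs, 3 higher and 8 lower in Null, with 1280 at an unadjusted p under 0.05 where chance gives 1007. They included Sirena1, Gm19248, Gm28438 (41.8 ± 5.14 against 73.6 ± 1.63 CPM, adjusted p = 0.0086), and, named after their values were seen, Gm11598 (0.50 ± 0.18 against 0.07 ± 0.04 CPM, adjusted p = 0.0157) and the tRNA gene mt-Tr. mt-Tr had 1 to 4 counts per Null library and 21 to 41 per WT library (adjusted p = 0.0137), and in GV oocytes 0 to 2 and 8 to 15. The count was 4 without MII WT replicate 1 or 2, 6 without MII WT replicate 3 and 7 without MII Null replicate 1; Elob, mt-Nd3 and Sirena1 passed with any library left out, Dhcr7 did not without MII WT replicate 1 or 3, Gm28438 and Gm11598 not without MII WT replicate 1, 2 or 3, Gm11598 also not without MII Null replicate 1, mt-Tr not without MII WT replicate 1 or 2 or MII Null replicate 1 or 2, Strap not without MII WT replicate 1 or 2 or MII Null replicate 1, 2 or 3, and Gm19276 not on leaving out any MII library except MII Null replicate 2. DESeq2 gave 42 genes (23 higher and 19 lower) and no filter 290 (232 higher and 58 lower), so the balance of directions turned. A minimum of 1.5-fold left 2, Sirena1 and Elob. A fit of only the MII groups gave 8 genes and lost Strap, Gm11598 and Gm19276.

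Of the 13 mitochondrially encoded mRNAs in eggs, 11 were above 0, with a median of 0.29 (camera adjusted p = 0.0293; adjusted p = 0.838 with an estimated correlation). Only mt-Nd3 passed over all genes, and adjusted over the list alone 3 were higher and 2 lower. mt-Co3 stood at 237 ± 48.7 CPM in Null and 152 ± 22.3 CPM in WT, and mt-Nd6 at 126 ± 11.1 and 151 ± 22.4 CPM. The share of counts was 1.19 ± 0.191% in Null (n = 4) and 0.990 ± 0.081% in WT (n = 3), a ratio of 1.21 (exact permutation p = 0.171). The list lost its call without MII Null replicate 1, 3 or 4 (adjusted p = 0.222, 0.0877 and 0.535) or MII WT replicate 1 or 3 (adjusted p = 0.316 and 0.0747).

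The 77 ribosomal protein genes had 66 members above 0 in eggs and a median of 0.26 (adjusted p = 6.08e-05; adjusted p = 0.838 with an estimated correlation), with Rpl32 at 15.8 ± 2.14 CPM in Null and 12.0 ± 1.79 CPM in WT. The 77 nuclear-encoded respiratory chain genes had 60 members above 0 and a median of 0.15 (adjusted p = 0.0145; adjusted p = 0.838 with an estimated correlation), with Cox7a2l at 9.65 ± 1.42 against 7.06 ± 0.93 CPM. Without MII Null replicate 1 the medians were 0.15 and 0.05 (adjusted p = 0.206 and 0.453), and without MII Null replicate 4 they were 0.12 and 0.05 (adjusted p = 0.535 and 0.652); the respiratory chain list also lost its call without MII WT replicate 1 or 3 (adjusted p = 0.0762 and 0.0811) and with the covariate (adjusted p = 0.0731). MII Null replicate 4 had the highest level of cumulus markers with a low background in oocytes, 25.5 CPM against 5.11 to 6.70 CPM in the other 3 MII Null libraries and 7.14 to 8.15 CPM in MII WT. The remaining 14 lists did not pass (smallest adjusted p 0.313, for the substrain markers, whose Entpd4 and Entpd4b were lower when adjusted over the list alone, at 1.5 ± 0.27 against 3.02 ± 0.54 CPM and 1.63 ± 0.27 against 3.19 ± 0.52 CPM). Irf3, of the interferon list, was lower when adjusted over the list alone (4.16 ± 0.19 against 6.11 ± 0.88 CPM). Nnt had 1, 5 and 4 counts in GV Null replicates 1, 2 and 3, and 0 counts in the other 10 libraries. Replicates 2 and 3 were those high in cumulus markers.

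Some genes passed at both stages. Elob and Gm11598 were higher in both, and 5 genes, among them Sirena1, Gm19248, mt-Nd3 and Gm28438, were lower in both. Independent lists of these sizes would share 0.000745 and 0.00238 genes, but these genes are not independent of each other. Sirena1 is the deleted gene, Gm19248 lies beside it, Gm28438 is described as a nuclear copy of mt-Nd3 (ratio of counts 1.01 in WT at both stages), and Gm11598 is an Elob pseudogene by background knowledge. Of 15 genes called at either stage, 7 were called at both, and 0 were called in opposite directions. Across 10307 genes with at least 5 CPM, which are not independent replicates, the fold changes of the stages correlated with Pearson r = 0.47 and Spearman rho = 0.27.

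A direct test asked whether the genotype effect differed between stages. Zfp385b alone passed: it was higher in Null GV oocytes (15.5 ± 0.41 against 8.47 ± 0.72 CPM), while eggs had 17.7 ± 1.77 CPM in Null and 20.7 ± 1.98 CPM in WT (difference in log2 -1.09, SE 0.16, adjusted p = 0.0406). An unadjusted p under 0.05 was found for 681 genes, where chance gives 1007. The next genes by adjusted p were Klf6, Flg, Zfp551, Cblb, Gm11408, Mfap4 and Fzd4, each with adjusted p = 0.999. Elob did not pass (difference in log2 0.31, SE 0.36, adjusted p = 0.999). The cumulus marker list passed (adjusted p = 0.00854; adjusted p = 0.812 with an estimated correlation) with 11 of 21 members above 0; camera gave it a downward direction while its median was 0.01 and its mean 0.14. None of the other 16 lists passed (smallest adjusted p 0.132). The call of Zfp385b ended, leaving 0 genes, with RLE scaling, with a minimum of 1.5-fold, and on leaving out any library except MII WT replicate 1, while its difference stayed between -1.16 and -1.01 over all 24 settings; DESeq2 gave 3 genes and no filter 157.

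Maturation from GV to MII in WT was compared to set the genotype effects beside the normal change; values are relative to the library total, since no spike-in count allowed an absolute scale. The largest rises among genes of at least 20 CPM were in mitochondrially encoded mRNAs and in the oocyte genes Omt2b and Omt2a. Omt2b rose 4.2-fold to 3038 ± 362 CPM and Omt2a 4.12-fold to 2767 ± 340 CPM (n = 3 per stage). Among the largest falls were Ccnd2, which encodes cyclin D2, from 61.7 ± 22.2 to 0.40 ± 0.18 CPM, and the ribosomal protein gene Rpl39, from 116 ± 20.3 to 1.24 ± 0.19 CPM. Rps13 fell from 102 ± 15.9 to 1.32 ± 0.38 CPM together with its pseudogenes Rps13-ps1, Rps13-ps2, Rps13-ps4 and Rps13-ps5, Rpl39-ps fell to 0.40 ± 0.03 CPM, and Atp5mpl, a small ATP synthase subunit, fell from 36.3 ± 4.82 to 0.75 ± 0.30 CPM. Reads shared between Rps13 or Rpl39 and their pseudogenes were not told apart, so these may not be separate falls.

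In all, 8609 genes changed in WT, 4014 higher and 4595 lower in eggs, with adjusted p of 0.000295 or less for the genes named by fold. Changes over 2-fold were mostly falls, 2926 against 220 rises. A minimum of 1.5-fold left 2707 genes. Upper-quartile scaling turned the balance, to 4826 higher and 4274 lower. DESeq2 gave no adjusted p for Rps13, whose log2 fold change over the other settings was -6.53 to -6.14 against -6.27.

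Genes for mitochondrial proteins moved apart by genome. All 13 mitochondrially encoded mRNAs rose, with a median log2 fold change of 1.77 (adjusted p = 3.00e-10; adjusted p = 0.196 with an estimated correlation). Among them mt-Nd4l rose 4.34-fold to 97.3 ± 10.3 CPM, mt-Nd2 4.19-fold, mt-Nd4 3.87-fold, mt-Atp8 3.81-fold, mt-Atp6 3.52-fold, mt-Nd3 3.47-fold, mt-Nd1 3.41-fold and mt-Nd6 2.98-fold. Both mitochondrial rRNAs rose, mt-Rnr1 1.95-fold and mt-Rnr2 1.57-fold (list adjusted p = 0.134). Of 77 nuclear-encoded respiratory chain genes 70 fell and 0 rose (median -2.17, adjusted p = 4.58e-28; adjusted p = 0.168 with an estimated correlation), such as the cytochrome oxidase gene Cox4i1, from 59.7 ± 5.29 to 3.20 ± 0.43 CPM, Cox7a2l, from 91.0 ± 5.91 to 7.06 ± 0.93 CPM, and Sdhd of complex II, from 107 ± 1.43 to 17.1 ± 2.3 CPM. Factors of mitochondrial gene expression and DNA maintenance went both ways, 4 up and 7 down of 25 (adjusted p = 0.402), with the mitochondrial RNA-binding protein gene Lrpprc at 46.4 ± 1.72 from 81.5 ± 1.84 CPM. Genes of mitochondrial distribution and dynamics did so too, 5 up and 7 down of 24 (adjusted p = 0.535), with the kinesin adaptor gene Trak2 at 13.6 ± 2.03 from 33.1 ± 5.39 CPM and the fission gene Fis1 at 2.16 ± 0.79 from 7.90 ± 0.07 CPM.

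Genes of the translation and mRNA decay machinery also moved as groups. Of 77 cytosolic ribosomal protein genes 72 fell and 1 rose (median -2.78, adjusted p = 4.10e-29; adjusted p = 0.196 with an estimated correlation), such as Rps21, from 33.2 ± 4.33 to 1.37 ± 0.26 CPM. Of 20 dormant maternal mRNAs, which are stored untranslated until maturation, 15 rose and 1 fell (median 0.41, adjusted p = 7.05e-05; adjusted p = 0.251 with an estimated correlation). Orc6, of the origin recognition complex, rose 1.69-fold, Btg4, a deadenylation adaptor, 1.65-fold to 1246 ± 76.6 CPM, and Cpeb1, a regulator of cytoplasmic polyadenylation, was the member that fell, from 854 ± 26.6 to 268 ± 27.5 CPM. Of 28 deadenylation and decapping genes 14 rose and 3 fell (median 0.21, adjusted p = 0.0122; adjusted p = 0.396 with an estimated correlation), with Cnot3 up 1.65-fold and Dcp1a up 1.48-fold; this list shares Btg4 and Dcp1a with the dormant mRNAs and did not pass with the filter of 5 CPM (adjusted p = 0.0661). Of 8 described endo-siRNA targets 6 fell (median -0.53, adjusted p = 0.0153; adjusted p = 0.168 with an estimated correlation), among them Elob, from 5.51 ± 0.85 to 0.85 ± 0.07 CPM, and Rangap1, from 10.3 ± 1.39 to 3.26 ± 0.60 CPM. Btg4, Cnot3 and Dcp1a did not pass with a minimum of 1.5-fold.

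The other lists did not pass camera during maturation in WT. Fry, which compares with no other genes, passed 12 of the 17 lists. Of those below it passed the stress response (fry adjusted p = 1.07e-05), Elongin and cullin ligase (0.000155) and oocyte-specific (0.00277) lists, and not the rest. It also passed the mitochondrial rRNAs (fry adjusted p = 0.00425), mitochondrial gene expression (0.00244) and mitochondrial dynamics (0.0189). Adjusted p values below are those of camera. Of 11 Elongin and cullin ligase genes 1 rose and 4 fell (adjusted p = 0.134), and Eloc, the partner of Elongin B, fell from 205 ± 18.6 to 58.2 ± 2.98 CPM. Of 14 RNA interference factors 3 rose and 2 fell (adjusted p = 0.452), and of 40 oocyte-specific and maternal-effect genes 14 rose and 16 fell (adjusted p = 0.556), with the nuclear chaperone Npm2 down from 383 ± 11.5 to 112 ± 3.21 CPM and Dppa3 down from 1109 ± 28.2 to 427 ± 34.9 CPM. Of 36 meiotic spindle genes 15 rose and 6 fell (adjusted p = 0.211), with Birc5, survivin, down from 326 ± 21.4 to 71.8 ± 3.00 CPM and Cdk1 down from 60.7 ± 3.83 to 17.5 ± 2.12 CPM. Of 22 stress response genes 3 rose and 9 fell (adjusted p = 0.245), with the mitochondrial chaperonin Hspe1 down from 55.6 ± 2.56 to 14.6 ± 1.55 CPM. Of 16 interferon response genes 5 rose and 2 fell (adjusted p = 0.878), of 21 cumulus markers 2 rose and 6 fell (adjusted p = 0.211), and of 7 substrain markers 1 rose and 1 fell (adjusted p = 0.417).

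**Figure D3:**
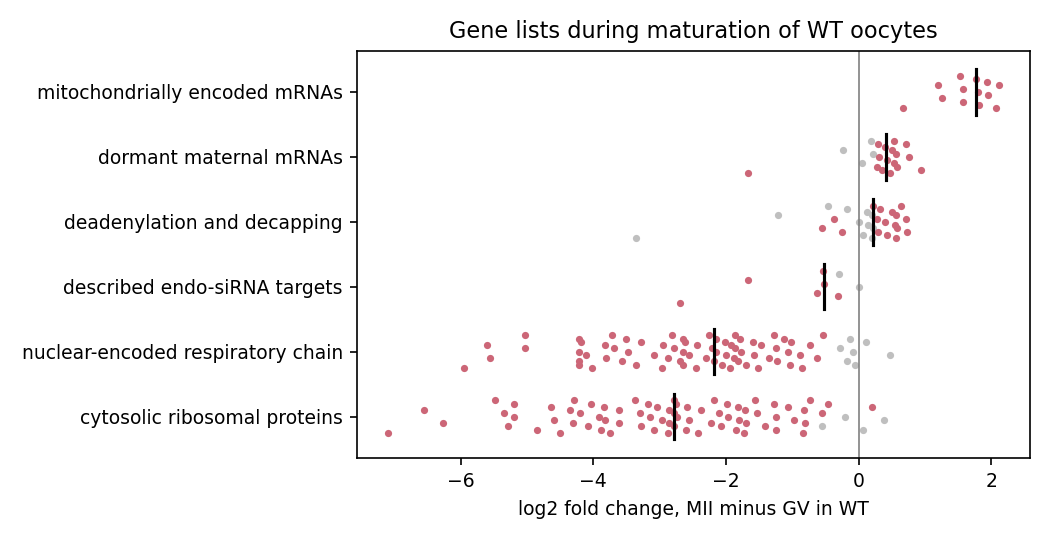
Log2 fold change of MII against GV in WT (horizontal axis) for the members of 6 gene lists, red where the adjusted p passed and grey where it did not, with black bars for list medians. Medians run from 1.77 for mitochondrially encoded mRNAs to -2.78 for cytosolic ribosomal protein genes.

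Maturation in Null oocytes changed largely the same genes. In Null, 9867 genes passed, 4456 higher and 5411 lower in eggs, or 5188 and 5019 with upper-quartile scaling. Of the genes that rose in WT, 3398 (84.7%) also rose in Null, where independent lists would share 888, and of those that fell 4069 (88.6%) also fell, where 1234 would be shared. The fold changes of the genotypes correlated across genes with r = 0.86. All 13 mitochondrially encoded mRNAs rose in Null (median 1.56, adjusted p = 2.22e-09; adjusted p = 0.202 with an estimated correlation), 73 of 77 ribosomal protein genes fell (median -2.76, adjusted p = 9.30e-28; adjusted p = 0.202 with an estimated correlation) and 71 of 77 respiratory chain genes fell (median -2.18, adjusted p = 1.27e-25; adjusted p = 0.202 with an estimated correlation). Of 20 dormant mRNAs 16 rose and 2 fell (adjusted p = 1.92e-05; adjusted p = 0.202 with an estimated correlation), and of 28 deadenylation and decapping genes 15 rose and 5 fell (adjusted p = 0.00288; adjusted p = 0.359 with an estimated correlation). The described endo-siRNA targets, which passed in WT, did not pass in Null (6 of 8 fell, median -0.33, adjusted p = 0.0524). Their change did not differ between genotypes by the interaction test (camera adjusted p = 0.365). Cumulus markers fell in 13 of 21 cases (median -3.51, adjusted p = 0.0132, or 0.523 with an estimated correlation), against 6 of 21 in WT, where the list did not pass. The GV Null libraries were uneven in low-background markers, with 558 and 165 CPM in replicates 2 and 3 and 19.5 CPM in replicate 1. The fall of this list was not tested without them, so it is not shown to belong to maturation. The count was 5672 with GV Null replicate 1 as the lone GV Null library, 6569 with the filter of 5 CPM and 3230 with a minimum of 1.5-fold.

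**Figure D4:**
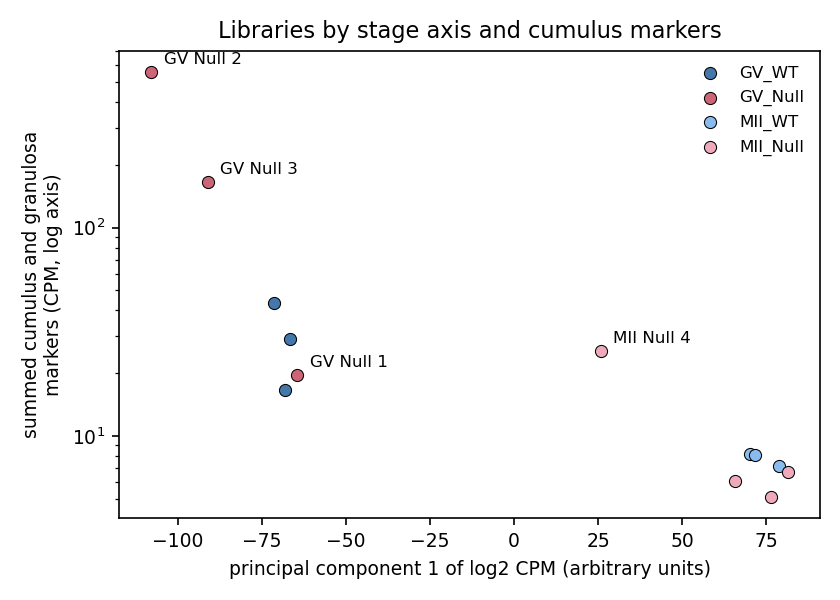
Leading principal component of log2 CPM (horizontal axis, arbitrary units) and summed CPM of cumulus and granulosa markers with a low background in oocytes (vertical axis, log scale) for the 13 libraries, by group. GV Null replicates 2 and 3 reach 558 and 165 CPM, and MII Null replicate 4 lies at 25.7 on the horizontal axis with 25.5 CPM.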

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

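The tests of explanations below, and the counts of other splits of the samples, were set down only after the results were seen.

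MII Null replicate 4 had 27065 detected genes, where the next library of its group had 25269 and the lowest 25157, so it stood apart from the other 3. Its summed level of cumulus markers with a low background in oocytes was 25.5 CPM, where the next had 6.70 and the lowest 5.11. These were 2 of 42 measures tested for a library that stands apart, and chance alone gives 2.1. Its place on the leading principal component did not pass the same test. MII Null replicate 1 was about as unlike its group in the chi-square between replicates. Pairs with replicate 1 had 28.2 to 31.5 per degree of freedom, and pairs with replicate 4 had 20.4 to 30.4. The genotype effect on Zfp385b differed between the stages by -1.09 on the log2 scale, by the interaction test. For the cumulus marker list the camera test of the same interaction gave an adjusted p of 0.00854, against 0.812 with an estimated correlation and 0.815 with fry. Camera gave the list a downward direction, while its median was 0.01 and its mean 0.14.

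Why MII Null replicate 4 lay between the stages was weighed with the genes that fall in maturation. Its excess over the other 3 MII Null libraries, as a share of the GV level, had a median of 7.09% in the 76 genes that fell over 16-fold (quartiles 5.63 and 8.93) and 6.81% in the 283 genes that fell 4- to 16-fold, while the other 3 libraries had -1.03%, -3.28% and -3.66% in the former. The like shares in these 2 classes are consistent with GV oocytes, or oocytes that had not matured, in this pool of 25. Only genes that fell over 16-fold set replicate 4 clear of the others: MII Null replicate 1 had 3.91% in genes that fell 4- to 16-fold and 8.02% in genes that fell 2- to 4-fold, above the 3.84% of replicate 4. Later maturation and RNA of cumulus cells cannot be told apart from it: the 3.84% in genes that fell 2- to 4-fold had quartiles of -3.75 and 10.7, and 10 oocyte-specific genes had 10.4% with quartiles of -9.60 and 18.8, too wide to decide. A biological difference of Null eggs is not tested by a single library.

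The fall of mt-Nd3 in Null was set against the rest of the mitochondrial transcripts. Fewer mitochondrial transcripts as a whole are argued against, since the other 12 mRNAs had medians of 0.50 in GV oocytes and 0.30 in eggs, with 12 and 11 of the 12 above 0. The pseudogene Gm28438, described as a nuclear copy of mt-Nd3, fell as well (log2 -1.01 in GV oocytes and -0.81 in eggs). Reads moved to Gm28438 would not lower it, so a move does not account for the whole fall. Counts of Gm28438 and mt-Nd3 were near equal in WT (ratio 1.01), as when the same reads are counted at both. Gm28438 then could not rise by a move, so its fall cannot tell whether part of the reads moved. Also open is mitochondrial DNA whose sequence differs between the genotypes. The ratio of Gm28438 to mt-Nd3 counts rose by at least 0.153, from 1.01 to 1.16 in GV oocytes and from 1.01 to 1.2 in eggs. The stratified exact permutation p was 0.00143, the smallest 700 arrangements can give (adjusted p = 0.00571). There was no overlap between 6 WT libraries (0.998 to 1.03) and 7 Null libraries (1.14 to 1.23). The ratios of Gm28437 to mt-Co3, Gm28661 to mt-Co2 and Gm10925 to mt-Atp6 moved by at most 0.011 (permutation adjusted p = 0.966, 0.606 and 0.794). Reads that align less well may thus lower the counts of mt-Nd3, and a fall of the transcript itself remains possible, since no sequence was available. The tRNA gene mt-Tr was lower in Null too, at low counts. It had 0 to 2 per Null and 8 to 15 per WT library in GV oocytes, and 1 to 4 and 21 to 41 in eggs. The list of substrain markers did not pass camera in GV oocytes (adjusted p = 0.776) or in eggs (adjusted p = 0.313). Its members Entpd4 and Entpd4b were lower in Null eggs when adjusted over the list alone. Levels of these few genes do not settle whether the WT and Null lines differ in strain background. Such a difference could not be told apart from the genotype.

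The higher level of the other mitochondrial mRNAs in Null was weighed next. The 10 most abundant genes held 5.70% to 7.71% of counts in the GV libraries, too little for their taking of counts to give a ratio of 1.42. The ratio of shares in GV oocytes was 1.44 without them, but their small share nearly fixed that outcome. Leaving them out also removed mitochondrial mRNAs among them, with the Null share at 0.353%, so this ratio is no separate evidence. RNA of cumulus cells cannot be told apart from the genotype: with the cumulus marker level as a covariate the median of the 12 mRNAs in GV oocytes was 0.34 (median SE 0.16) against 0.50 (median SE 0.17), and with GV Null replicate 1 as the lone Null library it was 0.25. In eggs the median was 0.25 without MII Null replicate 4. A biological effect of the genotype stays open, untested.

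Other splits of the samples into groups of the same sizes were fitted in the same way. In GV oocytes the real split gave 11 genes and the highest of the others 0, and in WT maturation 8609 and 0. Each had 10 splits, too few for a share under 0.05. In WT maturation every other split also put GV and MII libraries together in each group. The stage difference then widens the spread within groups, so the 0 was nearly fixed in advance and says little about chance. In eggs 2 of 35 splits gave as many genes as the real 11, so chance is not excluded for that count. It does not bear on each gene: 7 of the 11 also passed in the same direction in the GV libraries, Sirena1 among them (adjusted p = 3.43e-19 in eggs), though these 7 are not independent of each other. The highest other split, 31 genes, put MII Null replicates 1 and 4 with MII WT replicates 1 and 2. Whether a structure of the samples other than genotype lies behind that split was not tested. For maturation in Null, 1 of 35 splits, the real one, gave as many as 9867 genes. That share of 0.0286 is the smallest that 35 splits can give. Splits that put 1 MII Null library with all GV Null libraries gave 1072 to 6906 genes, so they still held much of the stage difference. The splits are thus a weak guide to chance there. For the difference between stages 1 of 40 drawn splits gave as many as the real 1 gene (highest other 0). That share is under 0.05, but it sets 1 gene, Zfp385b, against 0, its call ended in 18 of 24 settings (log2 -1.16 to -1.01 over all 24), and 681 genes had an unadjusted p under 0.05 where chance gives 1007, so little rests on it.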

How the results depend on the processing

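The settings without the 2 GV Null libraries high in cumulus markers (replicates 2 and 3), without these and MII Null replicate 4, and with the cumulus markers as a covariate were chosen after seeing the data, as were upper-quartile scaling and library sizes without mitochondrial genes for the gene lists. Causes were not tested unless a setting itself gives one, such as fewer genes tested or fewer libraries. Depth limits genes near 0.0727 to 0.0972 CPM, where 3 counts lie. Sirena1 kept its fall under all settings run (log2 -6.97 to -6.69 over both stages). The number of genes called at both stages, 7 in the main fit, was recomputed for few settings. It was 7 with an adjusted p below 0.1, 9 with DESeq2 and 6 with the replicate block. A minimum of 1.5-fold called only 3 genes in GV oocytes and 2 in eggs. Leaving out MII WT replicate 1 or 2 called 4 in eggs. Fewer than 7 could be shared in these settings. Scaling to the spike-in was not run, since the table holds no count for it. No scaling moved the median of all genes by over 0.1.

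With no filter on low counts, GV oocytes gave 644 genes, eggs 290 and the difference between stages 157, against 11, 11 and 1. With DESeq2 these were 24, 42 and 3. With a minimum of 1.5-fold they were 3, 2 and 0, and maturation gave 2707 genes in WT and 3230 in Null against 8609 and 9867. The filter of 5 CPM left 6569 for maturation in Null. RLE scaling and the cumulus covariate gave 0 for the difference between stages. Without the 2 GV Null libraries, GV oocytes gave 1 gene, the difference between stages 0 (0 also without MII Null replicate 4) and maturation in Null 5672; GV Null replicate 1 then stands alone and is assumed to vary like the other groups. Leaving out 1 library at a time gave 6 to 139 genes in GV oocytes, 4 to 12 in eggs, 0 to 1 for the difference, 7274 to 7529 in WT maturation and 8234 to 10217 in Null maturation. With the replicate number as a block, which does not pair the samples, the counts were 11, 12 and 0. A fit of only the groups compared gave 12 genes in GV oocytes and 8 in eggs.

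The mitochondrial mRNA list in GV oocytes (median 0.48) did not pass with an estimated correlation (0.48, adjusted p = 0.553), with fry (0.48, adjusted p = 0.275) or without the 2 GV Null libraries (0.23, adjusted p = 0.325; range over 16 settings 1.52e-10 to 0.553), where the ratio of shares was 1.15. Leave-outs of 1 library gave ratios of 1.3 to 1.56 in GV oocytes and 1.14 to 1.29 in eggs. In eggs the list (median 0.29) did not pass with an estimated correlation (0.29, adjusted p = 0.838), fry (0.29, adjusted p = 0.646), the replicate block (0.21, adjusted p = 0.566) or the covariate (0.25, adjusted p = 0.0800), nor in 5 of 7 fits without 1 library (medians 0.18 to 0.41 over the 7; adjusted p 0.00015 to 0.838 over 16 settings). The block also ended the calls in eggs of the ribosomal list (0.09 against 0.26, adjusted p = 0.566) and the respiratory chain list (0.03 against 0.15, adjusted p = 0.681). In WT maturation the mitochondrial mRNA list (median 1.77) did not pass with an estimated correlation (1.77, adjusted p = 0.196). With the 2 GV Null libraries left out, the medians in GV oocytes changed sign for dormant mRNAs (0.081), spindle genes (0.00245) and cumulus markers (-0.29), and with the covariate for spindle genes (0.00525).

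Over all settings, 1727 values of named genes and 671 of gene lists kept their direction and their side of the threshold (a list's count of called members within 1.5 times), 120 and 48 lost the call in the same direction, and 24 for genes gained it. DESeq2 gave no adjusted p for 2 genes, which are left out there. Elob in GV oocytes lost its call in 1 of 17 settings, the one without the 2 GV Null libraries (log2 1.79 against 2.03, adjusted p = 0.101, range 2.51e-27 to 0.101), where the fold stayed near as large and only GV Null replicate 1 was left, and in eggs in none of 17. mt-Nd3 lost it in 2 of 17 in GV oocytes (1.5-fold minimum and without the 2 libraries) and 1 of 17 in eggs (1.5-fold minimum), and Zfp385b for the difference between stages in 18 of 24 (log2 -1.16 to -1.01). Values near 0 changed sign: Tsg101 in GV oocytes with upper-quartile scaling (0.00135), the filter of 5 CPM (0.018), the covariate (0.057) and leave-outs (-0.048 to 0.027), and in eggs with RLE (0.00445), DESeq2 (0.00589), the block (0.034) and leave-outs (-0.10 to 0.054). mt-Nd6 in GV oocytes was -0.00359 without the 2 GV Null libraries, Gm32031 ranged from -0.18 (without GV WT replicate 1) to 0.52 over leave-outs, and Gm9999 in eggs from -0.72 to 0.011 (without MII WT replicate 3).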

Other observations

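Values in this part, apart from the counts of Nnt, and the choice of genes were taken after the results were seen. Copies of the Elob sequence had fold changes in the direction of Elob, but only Gm11598 passed at both stages. Gm8971 passed in GV oocytes and not in eggs (log2 1.99, adjusted p = 0.368). Gm11401 and Gm9238, which like Gm11598 and Gm8971 are Elob pseudogenes by background knowledge, had log2 fold changes of 2.07 and 2.04 in GV oocytes (adjusted p = 0.0931 and 0.0567) and of 2.68 and 2.76 in eggs (adjusted p = 0.435 and 0.291), beside 2.03 and 2.34 for Elob. Reads shared between these copies were not told apart, since the handling of reads that map to several places is not given.

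Tmem267 lies on chromosome 13 from 119488086 to 119610459, next to Nnt, from 119335527 to 119409257, a gene partly deleted in the C57BL/6J strain. Tmem267 was at 42.2 ± 6.66 CPM in Null eggs and 27.1 ± 1.14 CPM in WT eggs (log2 0.64, adjusted p = 0.368), after 33.4 and 13.1 CPM in GV oocytes. Nnt had 10 counts in total over the 3 GV Null libraries and 0 in each of the other groups, at or near the detection limit. These were 1, 5 and 4 counts in GV Null replicates 1, 2 and 3, and replicates 2 and 3 were high in cumulus markers. Whether they came from oocytes or from cumulus cells cannot be told. A second gene ID with the symbol Nnt had no counts.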
